A study of Homo sapiens with 9 samples.

How the data were processed

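RNA from MCF-7 cells was sequenced in 9 libraries, 3 each of Parental cells, cells overexpressing NFIB and cells overexpressing YBX1, grown in serum-containing medium. Per the labels' protocols the libraries were made with a stranded mRNA kit. Per the submitters' processing notes the tools were TopHat2 2.1.0 with Bowtie, featureCounts of Subread 1.5.1 and DESeq2 1.14.0 in R 3.3.2, on genome build GRCh37; the settings and the role of each tool were not given in the sources used here.

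The deposited table gave 1 signal value per gene and library for 35244 Ensembl genes, and its name calls the values normalized counts. In every library 100% of the values were whole multiples of 1 step, within a tolerance of 0.001 reads, so that whole reads could be recovered. The step equalled the median-of-ratios size factor of the recovered reads in all 9 libraries (ratio 1), with size factors of 0.792 to 1.13. The deposited values were thus reads multiplied by the size factor rather than divided by it. Their column sums ran from 38687999 to 75339926, a ratio of 1.95, and their medians over the tested genes from 281 to 567, a ratio of 2.01. The recovered reads were therefore divided by the size factors, after which these medians ran from 419 to 448, a ratio of 1.07. This departs from the chosen plan, which took the deposited values as depth-normalized, and results with the deposited values as they stand are given as an alternative. Recovered reads per library were 48838465 to 66622553. Counting intervals and bounds cover counting error only, since reads are not independent molecules.

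Genes were named from the supplied table of gene names, which matched 32719 of the 35244 identifiers; 32937 (93.5%) had a name from that or the supplied annotation. The annotation was of build GRCh38, so its coordinates are not given, and it was used only for names, gene types and the order of neighbouring genes. Genes with at least 10 normalized reads in at least 3 of the 9 libraries were tested, 21943 in all. The log2 of the normalized read count plus 1 was fitted with limma 3.58.1 in R 4.3.3 (limma-trend), all 9 libraries in 1 model with 1 mean per group, and the contrasts were NFIB against Parental, YBX1 against Parental and NFIB against YBX1. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as threshold. All tests were two-sided.

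The tests, the filter, 27 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The lists were estrogen-induced, estrogen-repressed, estrogen receptor and coregulators, FGF receptors and ligands, MAPK feedback targets, NFI and Y-box families, luminal epithelial, basal epithelial, mesenchymal and fibroblast, immune cells, G2/M phase, S phase, p53 targets, hypoxia, interferon-stimulated, MHC class I, unfolded protein response, heat shock, cholesterol synthesis, ribosomal proteins, NF-kB and chemokines, TGF-beta and BMP targets, reported YB-1 targets, AHR and NRF2 targets, mitochondrially encoded RNA, replication histones, and cell adhesion and migration. Some genes stand in more than 1 list, such as TFF3 and PCNA. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists of a comparison. List members TXNIP, FGF10, MIA, SOX10, TWIST2, CD3D, NKG7, MS4A1, TYROBP, UHRF1 and 3 histone genes matched no gene of the table.

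The naming rule took NFIB and YBX1, for each line against Parental the 12 largest rises and 12 largest falls, and for NFIB against YBX1 the 6 largest of each. These had an adjusted p under 0.05, a mean of at least 100 normalized reads in the higher group, no overlap between the libraries of the groups, and a proper symbol that is not a pseudogene. It also took up to 4 called members of each list, or up to 2 abundant ones where none was called, and 5 genes in each direction shared by both lines. Not every gene so chosen is printed. For genes with 1 to 3 Parental reads a ratio of reads with its 95% exact interval was computed.

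The overlap between the lines was set against 20 simulations of unchanged groups with shared controls. The model was tested on simulated data of 21943 genes with 200 changed genes in each line, 50 for each size of change. For NFIB against Parental 32%, 72%, 88% and 98% of genes changed 1.2-, 1.5-, 2- and 4-fold were called in the right direction and 2.68% of calls fell on unchanged genes. For YBX1 against Parental these values were 30%, 64%, 68% and 98%, with 1.52% of calls on unchanged genes. The real comparisons with Parental called 47.6% and 51.5% of genes, a far larger share than was changed here. The simulated rates therefore do not describe the real calls. No pair of libraries was a copy of another: the chi-square per gene between replicates was 6.63 to 47.9, where counting error alone gives 1.

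Alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50, TMM and quantile scaling, only the 6 libraries compared, a replicate block, sample weights, robust variance estimation, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and refits without each library. The deposited values as they stand and size factors without interferon genes and transgenes were added after the data were seen. Other splits of the libraries, neighbouring genes and lists of epidermal and amino acid response genes were examined in addition. Raw sequence reads were not used here.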

Results

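Gene expression was measured by stranded mRNA sequencing in MCF-7, an estrogen receptor-positive human breast cancer cell line, in 3 forms with 3 libraries each. Parental cells were untransfected, the NFIB line carried a stable FLAG-tagged NFIB transgene, and the YBX1 line carried a stable FLAG-tagged YBX1 transgene. Per the series description the replicates were separate clones, and per the labels only the overexpressing lines grew with geneticin; a line with an empty plasmid was not given in the sources used here. The libraries held 48838465 to 66622553 reads assigned to genes, with means of 60408412 ± 3247398 for Parental, 61529326 ± 6826754 for NFIB and 58422375 ± 8355389 for YBX1 (SD, n = 3). Mitochondrially encoded RNA took 3.96 ± 0.923%, 3.57 ± 0.686% and 4.18 ± 1.46% of these reads. Values below are reads divided by each library's size factor, called normalized read counts, as mean ± SD of 3 libraries, and fold changes are on the log2 scale with their standard error (SE). The typical variation between replicates beyond counting error was 5.14% for Parental, 4.40% for NFIB and 6.32% for YBX1. On the first principal component, with 64.1% of the variance, Parental libraries lay between -74.1 and -66.2 and both overexpressing lines between 30.2 and 37.7. The second component (10.8%) placed NFIB libraries between -28.5 and -21.5 and YBX1 libraries between 17.9 and 27.2.

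NFIB, a transcription factor of the nuclear factor I family, was at 2756 ± 399.7 normalized reads in Parental (ENSG00000147862, chromosome 9) and at 1268349 ± 121323 in the NFIB line. It rose by 8.85 (SE 0.20, limma adjusted p = 3.61e-15) and took 2.11% of all reads there, against 0.00472% in Parental. In the YBX1 line NFIB was at 3552 ± 1684 (difference 0.28, adjusted p = 0.270), with YBX1 replicate 3 the highest at 0.00904% of its reads. YBX1, a DNA- and RNA-binding protein with a cold shock domain, was at 14021 ± 1476 in Parental (ENSG00000065978, chromosome 1) and at 333275 ± 35743 in the YBX1 line. It rose there by 4.57 (SE 0.08, adjusted p = 7.48e-17), 23.8-fold, and took 0.555% of reads against 0.0239% in Parental. YBX1 differed by -0.02 (adjusted p = 0.888) between the NFIB line and Parental. Each of the 3 libraries labelled NFIB lay above every other library for NFIB, and each of the 3 labelled YBX1 above every other library for YBX1, as the plot of selected genes by library shows.

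**Figure D1:**
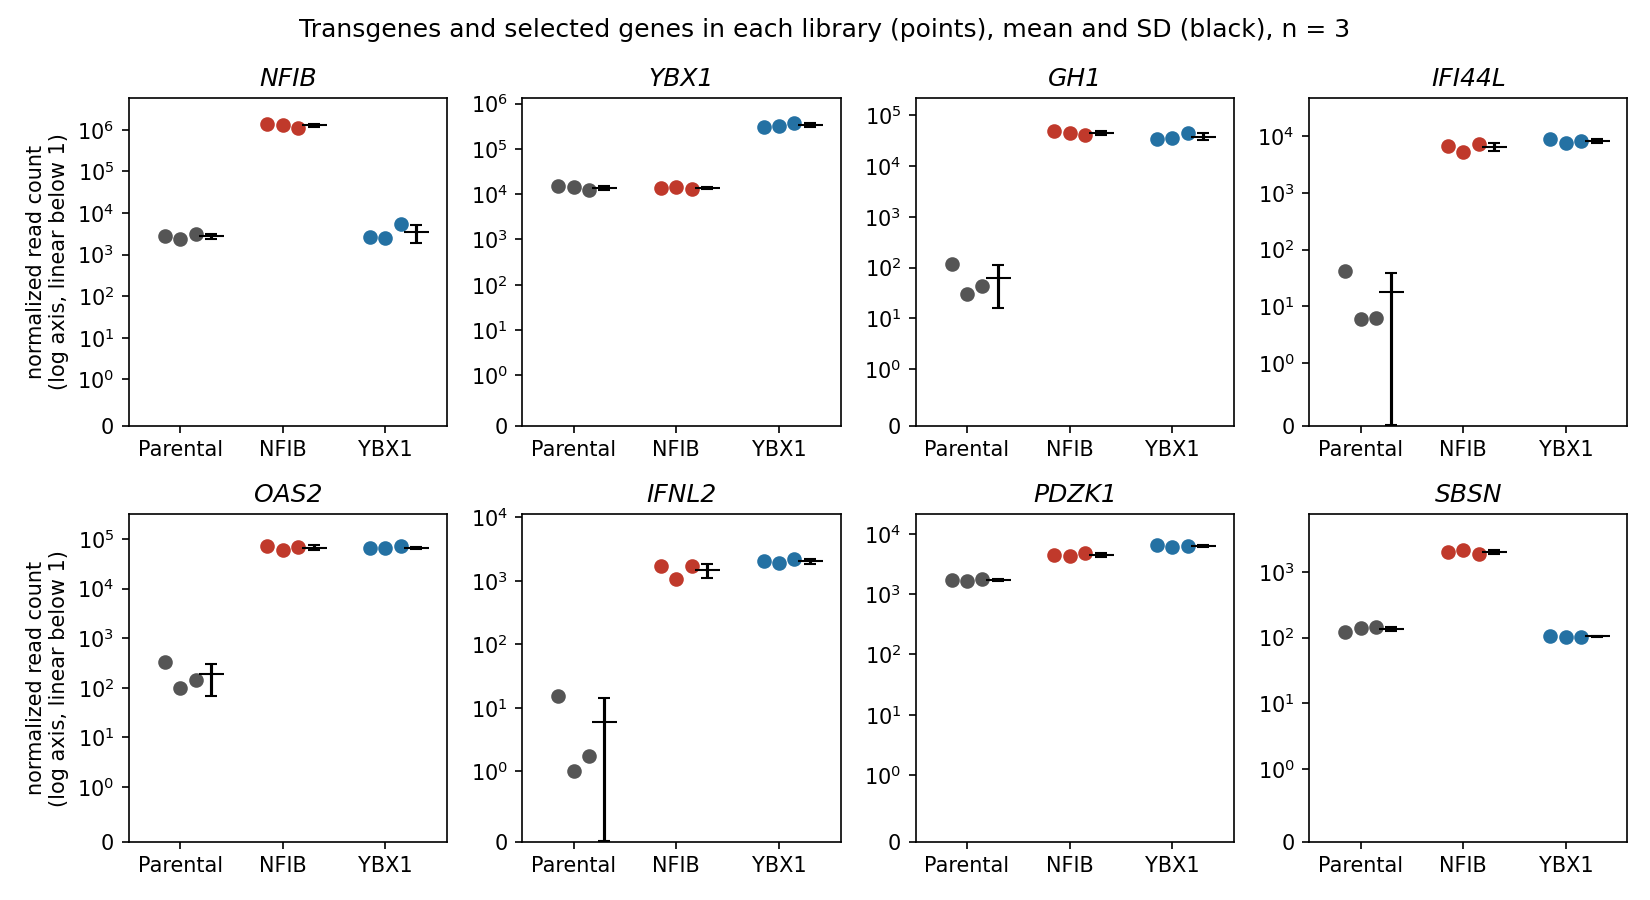
Normalized read count (vertical axis, logarithmic above 1 and linear below) of 8 genes in each of the 9 libraries; points are libraries, bars are group means with SD (n = 3), and an SD that would pass below 0 stops at 0. NFIB was at 1268349 in the NFIB line and YBX1 at 333275 in the YBX1 line, GH1, IFI44L, OAS2 and IFNL2 were high in both lines, PDZK1 was at 1722 in Parental, 4509 in NFIB and 6375 in YBX1, and SBSN was at 1996 in the NFIB line against 135 in Parental and 104 in YBX1.

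The comparison of the NFIB line with Parental asks which genes differ when NFIB is raised, in a study of NFIB and YBX1 as partners of the estrogen receptor and of FGFR2 signalling. The interferon-response genes rose most, together with GH1, which encodes pituitary growth hormone. GH1 (ENSG00000259384, chromosome 17) rose by 9.68 (SE 0.31, limma adjusted p = 3.11e-13), from 63.9 ± 48.0 to 44825 ± 3905 normalized reads. IFI44L rose by 8.97 (SE 0.44, adjusted p = 1.33e-10), from 17.7 ± 20.1 to 6494 ± 1051, and OAS2, an antiviral enzyme, rose by 8.66 (SE 0.27, adjusted p = 1.93e-13), from 187 ± 120.1 to 67298 ± 6954. CLGN, a chaperone gene, fell by 2.51 (SE 0.20, adjusted p = 5.99e-08), from 609 ± 89.3 to 106 ± 18.4. NIBAN1, a stress-responsive gene, fell by 2.06 (SE 0.18, adjusted p = 9.77e-08), from 2456 ± 498 to 597 ± 177. ALDH1L2, an enzyme of mitochondrial folate metabolism, fell by 1.75 (SE 0.09, adjusted p = 3.91e-10), from 1497 ± 112 to 445 ± 40.5.

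The other genes with the largest rises in the NFIB line were IFNL2 (8.33) and IFNL3 (8.20), near-identical interferon lambda genes whose reads cannot be divided with certainty, IFI27 (8.04), IFI44 (7.98), IFIT3 (7.94), CMPK2 (7.93), RSAD2 (7.89) and IFIT1 (7.86). In Parental, IFNL2 had only 18 reads in all, at 15.4 normalized reads in replicate 1 against 1.01 and 1.78 in replicates 2 and 3. IFIT1B had 3 reads over the Parental libraries and 1916 over the NFIB libraries, a ratio of 643 with a 95% counting interval of 220 to 3123. The other large falls were DMGDH (-2.37), DRD1 (-1.90), TRPV6 (-1.78), B3GNT5 (-1.75), UNC5B (-1.73), KCNJ12 (-1.70), OVOL2 (-1.63), GABBR2 (-1.62) and BEX2 (-1.58). For each of these genes the 3 NFIB libraries and the 3 Parental libraries did not overlap, which the naming rule required. Of 21943 genes tested with limma, 10442 (47.6%) differed between NFIB and Parental, 5348 higher and 5094 lower. The median size of a called change was 0.39, and 1305 genes changed by at least 1, with 1063 higher and 242 lower. With the deposited values left as they stand, 871 genes were called, 86.2% of them higher against 51.2% here. Quantile normalization turned the balance, with 4561 higher and 6193 lower (42.4% higher).

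Of the 27 fixed gene lists, the interferon response changed most in the NFIB line. All 29 tested members of the interferon-stimulated list rose in the NFIB line, with a median of 6.84 (a 115-fold rise, camera adjusted p = 1.48e-41, and adjusted p = 0.179 with an estimated correlation), and the list's share of all reads was 0.0315% in Parental and 1.25% in NFIB. All 12 MHC class I genes rose (median 3.34, adjusted p = 7.48e-18, and adjusted p = 0.179 with an estimated correlation), among them the peptide transporter TAP1 (4.46), PSMB8 (6.76), PSMB9 (6.51) and NLRC5 (5.87). All 13 tested of 17 members of the NF-kB and chemokine list rose (median 2.90, adjusted p = 8.76e-11, and adjusted p = 0.194 with an estimated correlation). Of these, 2 had no Parental reads and 3 had 1 to 3, so they passed the filter only through the overexpressing lines. The median was the same with those without Parental reads at their counting bounds. The list member TNFAIP3, an inhibitor of NF-kB, rose by 3.71 (SE 0.10, adjusted p = 4.87e-14), from 80.1 to 1068. IL6 had 2 Parental reads and 308 NFIB reads, a ratio of 155 (interval 42.6 to 1287), CXCL8 had 2 and 202, a ratio of 102 (27.8 to 846), and CCL2 had 0 and 35, at least 9.06-fold higher by the 95% counting bound. The counts in this and the following list paragraphs on NFIB and Parental were the same when adjusted over the list alone, except where given.

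Chaperone, cholesterol, DNA replication and hypoxia genes also rose in the NFIB line, by less. Of the heat shock list 11 of 12 members rose (median 0.60, camera adjusted p = 1.91e-08, and adjusted p = 0.194 with an estimated correlation), led by the HSP40 gene DNAJA1 at 1.51 (SE 0.04, adjusted p = 3.64e-14, 4650.0 ± 116 to 13202 ± 72.1) and HSPA8 at 1.06; HSPA1A and HSPA1B, near-identical copies, were at 1.25 each. Of the cholesterol synthesis list 17 of 19 members rose, 18 when adjusted over the list alone (median 0.57, adjusted p = 1.83e-10, and adjusted p = 0.328 with an estimated correlation), including STARD4 (0.98), MVD (0.97) and INSIG1 (0.92). Of the S phase list 16 of 18 members rose, 17 when adjusted over the list alone (median 0.43, adjusted p = 1.12e-07, and adjusted p = 0.367 with an estimated correlation), including CCNE2 (1.06), PCNA (0.59) and MCM4 (0.56). Of the hypoxia list 15 of 17 members rose (median 0.64, adjusted p = 3.08e-05, adjusted p = 0.559 with an estimated correlation and 0.0573 with DESeq2), including PFKFB4 (1.85), ADM (1.83) and EGLN3 (1.62). In the basal epithelial list 11 of 18 members rose and 3 fell (median 0.40, adjusted p = 0.0243, and adjusted p = 0.367 with an estimated correlation). KRT17 was at 2.01, KRT6B at 1.39 and TP63 at -1.002. The basal call also ended with edgeR (0.165), DESeq2 (0.186) and the deposited scaling (0.159), and that of the S phase list with the deposited scaling (0.101). Across the alternatives, adjusted p ranged from 2.37e-08 to 0.559 for hypoxia, from 0.00392 to 0.367 for the basal list and from 5.62e-11 to 0.367 for the S phase list.

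Most members of the ribosomal protein, G2/M phase, p53 target and estrogen-repressed lists fell in the NFIB line. Of the ribosomal protein list 43 of 48 members fell and 1 rose, 44 and 1 when adjusted over the list alone (median -0.28, camera adjusted p = 1.34e-13, and adjusted p = 0.369 with an estimated correlation). RPL5 was at -0.72 and RPL3 at -0.61. In the G2/M list 13 of 20 fell and 5 rose (median -0.23, adjusted p = 0.00823, adjusted p = 0.559 with an estimated correlation and 0.219 with the deposited scaling). TOP2A, a topoisomerase of dividing cells, fell by 0.69 (SE 0.04, adjusted p = 3.82e-09), and CCNB2 rose by 0.38 (SE 0.06, adjusted p = 4.17e-05). In the p53 target list 10 of 18 fell and 3 rose (median -0.19, adjusted p = 0.0269, adjusted p = 0.619 with an estimated correlation, 0.0872 with edgeR, 0.0743 with DESeq2, 0.0624 with a filter of 50 and 0.277 with the deposited scaling). DDB2 was at -0.47 and TP53I3 at 0.55. In the estrogen-repressed list 7 of 10 fell and 1 rose (median -0.25, adjusted p = 0.0243, adjusted p = 0.194 with an estimated correlation, 0.0566 with a filter of 50 and 0.168 with the deposited scaling). BMF was at -1.52 and EFNA1 at 0.49. Ranges of the adjusted p over all alternatives were 0.000742 to 0.559 for the G2/M list, 0.00413 to 0.619 for p53 targets and 0.00377 to 0.194 for estrogen-repressed genes.

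The estrogen-induced list, which bears on the question of the study, split in the NFIB line: 19 of 41 members rose and 14 fell, 20 and 14 when adjusted over the list alone (median 0.13, camera adjusted p = 0.330). PDZK1, a scaffold protein gene induced by estrogen, rose by 1.39 (SE 0.05, adjusted p = 2.27e-12), from 1722 ± 60.8 to 4509 ± 292, NPY1R rose by 0.87 and AREG fell by 0.75. Of the receptor and coregulator list 5 of 19 rose and 4 fell, 2 without Parental replicate 1 (median 0.04, adjusted p = 0.561). AR was at 0.48 and GATA3 at -0.27. In the FGF receptor and ligand list 6 of 10 members rose, 3 without Parental replicate 2 or NFIB replicate 3 (median 0.24, adjusted p = 0.143), including FGFR4 (0.39) and FGFR3 (0.34). FGFR2 was at 325 ± 35.7 in Parental and 397 ± 46.0 in NFIB, a difference of 0.29 (SE 0.11, adjusted p = 0.0489). That call ended without Parental replicate 1 (0.106), Parental replicate 2 (0.182), NFIB replicate 2 (0.108), NFIB replicate 3 (0.202) or YBX1 replicate 3 (0.0567). FGF18, at 3.91 normalized reads in Parental and 11.6 in NFIB, differed by 1.53 (adjusted p = 0.0174), and by 0.99 without Parental replicate 2 (adjusted p = 0.0908) or 1.29 without NFIB replicate 3 (adjusted p = 0.0815). FGFR2's adjusted p ranged over all alternatives from 0.0222 to 0.978 and that of FGF18 from 0.00424 to 0.145. In the MAPK feedback list 8 of 17 rose and 6 fell (median 0.22, adjusted p = 0.473). SPRY4 was at 0.93 and ETV5 at -1.003.

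The remaining lists were not called by camera on limma's fit in the NFIB line. The NFI and Y-box family list held 3 genes that rose and 3 that fell out of 7 (median -0.02, mean 1.34 and test direction up, adjusted p = 0.553, but 2.03e-07 with the deposited scaling, and 2.03e-07 to 0.726 over all alternatives). NFIX was at 1.39 and YBX2 at -0.54. The genes that rose include NFIB itself, at 8.85, so the result of this list is not independent of the transgene. The luminal list had 7 of 19 higher and 5 lower (median 0.01, and -0.02 with the deposited scaling, adjusted p = 0.825). MUC1 was at 0.69. The mesenchymal list had 5 of 11 higher and 1 lower (median 0.46, adjusted p = 0.0665). SNAI1 was at 0.91, and the list's adjusted p was 0.0442 without Parental replicate 3 and 0.0400 without NFIB replicate 1. The unfolded protein response list had 9 of 15 lower and 5 higher (median -0.24, adjusted p = 0.0665, 0.0296 with edgeR, 0.0364 with DESeq2, 0.0149 with no filter and 0.0244 without NFIB replicate 1). ASNS was at -1.09 and DDIT3 at -1.06, while the highest member stood at 0.66. The adjusted p ranged over the alternatives from 0.0400 to 0.403 for the mesenchymal list and from 0.0149 to 0.631 for the unfolded protein response list. The TGF-beta and BMP list had 5 of 14 higher and 4 lower, 2 lower without NFIB replicate 3 (median -0.00, above 0 with TMM and edgeR, mean 0.03 and test direction down, adjusted p = 0.825). PMEPA1 was at -0.80. The list of reported YB-1 targets had 6 of 11 lower and 4 higher, 2 higher without NFIB replicate 2 (median -0.20, adjusted p = 0.143). MYC was at -0.61. The AHR and NRF2 list had 8 of 12 higher and 3 lower (median 0.18, adjusted p = 0.438). AHRR was at -1.55 and HMOX1 at 0.996. The replication histone list had 5 of 8 lower and 2 higher (median -0.33, adjusted p = 0.143). H2AC6 was at -0.97. The adhesion and migration list had 9 of 19 higher and 5 lower (median 0.12, adjusted p = 0.336). MMP13 was at 2.11 and PLAUR at 1.91.

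Among markers of other sources, the mitochondrially encoded list had 2 of 15 members lower in the NFIB line over all genes tested by limma and 0 when adjusted over the list alone, 2 with edgeR and 0 with DESeq2 (median 0.03, mean -0.10 and test direction down, adjusted p = 0.731). MT-ND2 was at -0.98 (adjusted p = 0.0197) and MT-CO3 at -0.78 (adjusted p = 0.0175), and leaving out Parental replicate 1, Parental replicate 2 or NFIB replicate 3 ended both calls (0.0823, 0.0764 and 0.120 for MT-ND2, 0.0696, 0.0722 and 0.108 for MT-CO3). MT-ND2 ranged in adjusted p from 0.00367 to 0.168 over all alternatives, and MT-CO3 from 0.00279 to 0.155. The immune cell list had 2 of 7 members higher, 1 when adjusted over the list alone (median 0.13, and -0.08 with quantile normalization, adjusted p = 0.553). ITGAM was at 3.504 normalized reads in Parental and 36.9 in NFIB. CD68 was at 3.85 and 10.1 (adjusted p = 0.0340), and its call ended without Parental replicate 1 (0.0595), Parental replicate 2 (0.0961), NFIB replicate 2 (0.0954) or NFIB replicate 3 (0.102), with a range of 0.0201 to 0.159 over all alternatives. The common leukocyte antigen PTPRC stood at 3.64 in Parental and 3.04 in NFIB, and LYZ at 34.9 and 30.1. None of the list calls on NFIB and Parental held at an adjusted p of 0.05 with an estimated correlation. Because the Parental cells were neither transfected nor grown with geneticin, this comparison holds those differences together with that of NFIB.

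The comparison of the YBX1 line with Parental asks the same question for YBX1. The same groups led: interferon-response genes and GH1 rose most, and NIBAN1, CLGN and TSC22D3 were among the largest falls. GH1 rose by 9.43 (SE 0.31, limma adjusted p = 4.49e-13) to 38016 ± 5994.5 normalized reads, IFI44L rose by 9.33 (SE 0.44, adjusted p = 6.96e-11) to 8281 ± 586, and IFI27, an interferon-induced membrane protein gene, rose by 8.60 (SE 0.23, adjusted p = 3.80e-14), from 76.5 ± 42.9 to 27508 ± 1237. NIBAN1 fell by 3.62 (SE 0.18, adjusted p = 9.60e-11), from 2456 ± 498 to 197 ± 26.8. TSC22D3, a glucocorticoid-induced gene, fell by 2.11 (SE 0.07, adjusted p = 9.65e-13), from 9264 ± 191 to 2144 ± 202.

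Further large rises in the YBX1 line were IFNL2 (8.83) and IFNL3 (8.71), which share reads as above, OAS2 (8.67), IFI44 (8.02), IFIT3 (7.95), IFI6 (7.79), XAF1 (7.72) and IFIT1 (7.69). IFIT1B had 3 reads in Parental and 1585 in YBX1, a ratio of 559 with a 95% counting interval of 191 to 2713. Further large falls were DMGDH (-3.49), CLGN (-3.42), TRPV6 (-2.70), the coagulation factor gene F7 (-2.67), B3GNT5 (-2.26), SLITRK6 (-2.13), VLDLR-AS1 (-2.12), DRD1 (-2.06), ALDH1L2 (-2.05) and BEST1 (-2.03). Limma called 11306 of 21943 genes (51.5%) between YBX1 and Parental, 5827 higher and 5479 lower. The median size of a called change was 0.43, and 1544 genes changed by at least 1, with 989 higher and 555 lower. The deposited scaling, which moved the median of all genes by -0.18 in this comparison, gave 1167 calls, 603 higher and 564 lower, and quantile normalization gave 5065 higher and 6319 lower.

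Of the fixed lists, the interferon-stimulated list rose in the YBX1 line in all 29 members (median 6.77, a 109-fold rise, camera adjusted p = 3.00e-36, and adjusted p = 0.153 with an estimated correlation). All 12 MHC class I genes rose (median 3.53, adjusted p = 7.05e-16, and adjusted p = 0.153 with an estimated correlation). TAP1 was at 4.32. All 13 tested members of the NF-kB and chemokine list rose (median 3.38, adjusted p = 1.02e-10, and adjusted p = 0.164 with an estimated correlation). The median was the same with members without Parental reads at counting bounds. Members with few Parental reads passed the filter only through the overexpressing lines, as above. TNFAIP3 was at 4.51, from 80.1 to 1859. IL6 had 2 Parental reads and 445 YBX1 reads, a ratio of 235 (interval 64.8 to 1950.0), CXCL8 had 2 and 320, a ratio of 169 (46.5 to 1404), and CCL20 had 2 and 101, a ratio of 53.4 (14.4 to 447). All 12 heat shock genes rose (median 0.94, adjusted p = 5.28e-10, and adjusted p = 0.157 with an estimated correlation). HSPA8 was at 1.57 (SE 0.05, adjusted p = 1.54e-13) and DNAJA1 at 1.56. Of the S phase list 17 of 18 rose (median 0.61, adjusted p = 1.51e-09, and adjusted p = 0.387 with an estimated correlation). CCNE2 was at 1.07 and PCNA at 0.83. Of the cholesterol list 18 of 19 rose (median 0.61, adjusted p = 1.60e-08, and adjusted p = 0.391 with an estimated correlation). MVD was at 0.88 and SQLE at 0.81. Of the ribosomal list 33 of 48 fell and 3 rose, 34 and 3 when adjusted over the list alone (median -0.18, adjusted p = 7.93e-07, and adjusted p = 0.563 with an estimated correlation). RPL5 was at -0.73. Counts in the YBX1 list paragraphs were the same when adjusted over the list alone, except where given.

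The estrogen lists were both called in the YBX1 line. Of the estrogen-induced list 24 of 41 members rose and 10 fell (median 0.24, camera adjusted p = 0.00600, adjusted p = 0.410 with an estimated correlation, 0.204 with the deposited scaling, and 0.000271 to 0.410 over all alternatives). PDZK1 rose by 1.89 (SE 0.05, adjusted p = 3.37e-14) to 6375 ± 224, HSPB8 by 1.13 (SE 0.08, adjusted p = 4.15e-09) and CXCL12, a chemokine gene, by 1.07 (SE 0.06, adjusted p = 1.24e-09), from 907 ± 71.0 to 1902 ± 4.68. TFF3, a secreted trefoil peptide gene, fell by 1.142 (SE 0.11, adjusted p = 3.14e-07). Of the estrogen-repressed list 7 of 10 fell and 1 rose (median -0.49, adjusted p = 0.00477, adjusted p = 0.153 with an estimated correlation and 0.0705 with the deposited scaling, 0.000271 to 0.153 over all alternatives). BMF was at -1.14, TP53INP1 at -0.79 and EFNA1 at 0.68. The receptor and coregulator list had 6 of 19 higher and 6 lower (median -0.00, mean 0.02 and test direction up, adjusted p = 0.894). PGR was at 0.40 and SPDEF at -0.35. FGFR2 rose by 0.44 (SE 0.11, adjusted p = 0.00435), to 441 ± 63.0, in an FGF list with 4 of 10 higher, 2 without Parental replicate 2, and 1 lower (median 0.20, adjusted p = 0.287). FGF18 was at 1.60 (adjusted p = 0.0120, 1.07 with adjusted p = 0.0632 without Parental replicate 2, and an adjusted p of 0.00282 to 0.129 over all alternatives). The MAPK feedback list had 8 of 17 lower and 5 higher, 8 and 6 when adjusted over the list alone (median 0.09, -0.10 with the deposited scaling, mean 0.03 and test direction down, adjusted p = 0.661). FOSL1 was at 1.48 and DUSP6 at -1.29.

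In the unfolded protein response list 9 of 15 members fell in the YBX1 line and 4 rose (median -0.41, camera adjusted p = 0.0457, and adjusted p = 0.563 with an estimated correlation). ASNS, asparagine synthetase, was at -1.65 and CHAC1 at -1.51, while the highest member stood at 1.33. The call on this list ended without Parental replicate 2 (0.0502), NFIB replicate 2 (0.0590) or YBX1 replicate 1 (0.0742), and with a filter of 50 (0.0824) or sample weights (0.0547). The replication histone list had 5 of 8 lower and 1 higher (median -0.37, adjusted p = 0.0439, and adjusted p = 0.563 with an estimated correlation). H2AC6 was at -1.19, and the list's call ended without Parental replicate 2 (0.0510) or YBX1 replicate 1 (0.108), and with a filter of 50 (0.0787), sample weights (0.0730) or the deposited scaling (0.0896). The hypoxia list had 9 of 17 higher and 2 lower (median 0.39, adjusted p = 0.0697). PFKFB4 was at 1.75. The hypoxia list was called without Parental replicate 3 (0.0189), YBX1 replicate 1 (0.0267) or YBX1 replicate 3 (0.00836). It was also called with no filter (0.0127), quantile normalization (0.0415) and a replicate block (0.0483). It was not called in the other refits, that without YBX1 replicate 2 among them. YBX1 replicate 2 was the highest YBX1 library in all 17 hypoxia genes. NDRG1, for example, was at 18034 there, against 6720 and 6048 in the other YBX1 libraries and 6740 to 11061 in Parental. PFKFB4, in contrast, was above Parental (682 to 1002) in each YBX1 library (2148 to 4022). Over all alternatives the adjusted p ranged from 0.00400 to 0.563 for the unfolded protein response list, from 0.0188 to 0.563 for the histone list and from 0.00836 to 0.707 for the hypoxia list. Lists that camera did not call were G2/M (9 of 20 higher, 6 lower, median 0.08, and -0.11 with the deposited scaling, 0.325), p53 targets (5 of 18 higher, 3 without YBX1 replicate 3, and 9 lower, -0.09, 0.266), luminal (6 of 19 higher, 9 lower, -0.09, 0.325) and mesenchymal (4 of 11 higher, 1 lower, 0.39, 0.294). The basal list (8 of 18 higher, 3 lower, 0.09, and -0.10 with the deposited scaling, 0.287) and the adhesion list (9 of 19 higher, 4 lower, 0.18, and -0.00 with the deposited scaling, 0.294) were not called either. The same held for NFI and Y-box genes (3 of 7 higher, 2 lower, 0.28, 0.294, but 0.00854 with edgeR, 0.00729 with DESeq2 and 0.00918 with the deposited scaling, and 0.00729 to 0.563 over all alternatives), TGF-beta targets (2 of 14 higher, 6 lower, 3 and 7 when adjusted over the list alone, -0.13, 0.294), reported YB-1 targets (2 of 11 higher, 5 lower, -0.12, 0.148) and AHR and NRF2 targets (8 of 12 higher, 2 lower, 0.23, 0.148). Among these, CDC20 rose by 0.70 and MKI67 by 0.54, KRT17 rose by 2.38, ERBB2 fell by 0.62 and SLC7A11 fell by 1.55. The NFI and Y-box list holds YBX1 itself, at 4.57, so its result is not independent of the transgene.

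Of the mitochondrially encoded list 4 of 15 members were higher and 2 lower in the YBX1 line, 0 higher and 2 lower when adjusted over the list alone (median 0.16, and -0.03 with the deposited scaling, adjusted p = 0.771). MT-ND2 was at -1.41 and MT-CO3 at -1.24. The 4 higher calls ended without Parental replicate 3, NFIB replicate 1, YBX1 replicate 2 or YBX1 replicate 3, and became 1 without NFIB replicate 2 and 9 without YBX1 replicate 1. The immune cell list had 2 of 7 higher and 1 lower, 3 and 1 when adjusted over the list alone (median 0.43, adjusted p = 0.447). ITGAM was at 33.9 normalized reads, CD14 at 15.4 against 3.35 in Parental, CD68 at 9.89 (adjusted p = 0.0528), LYZ at 40.0 and PTPRC at 2.62. None of the list calls on YBX1 and Parental held at an adjusted p of 0.05 with an estimated correlation. Transfection and geneticin differ between the YBX1 line and Parental as they do for the NFIB line.

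**Figure D2:**
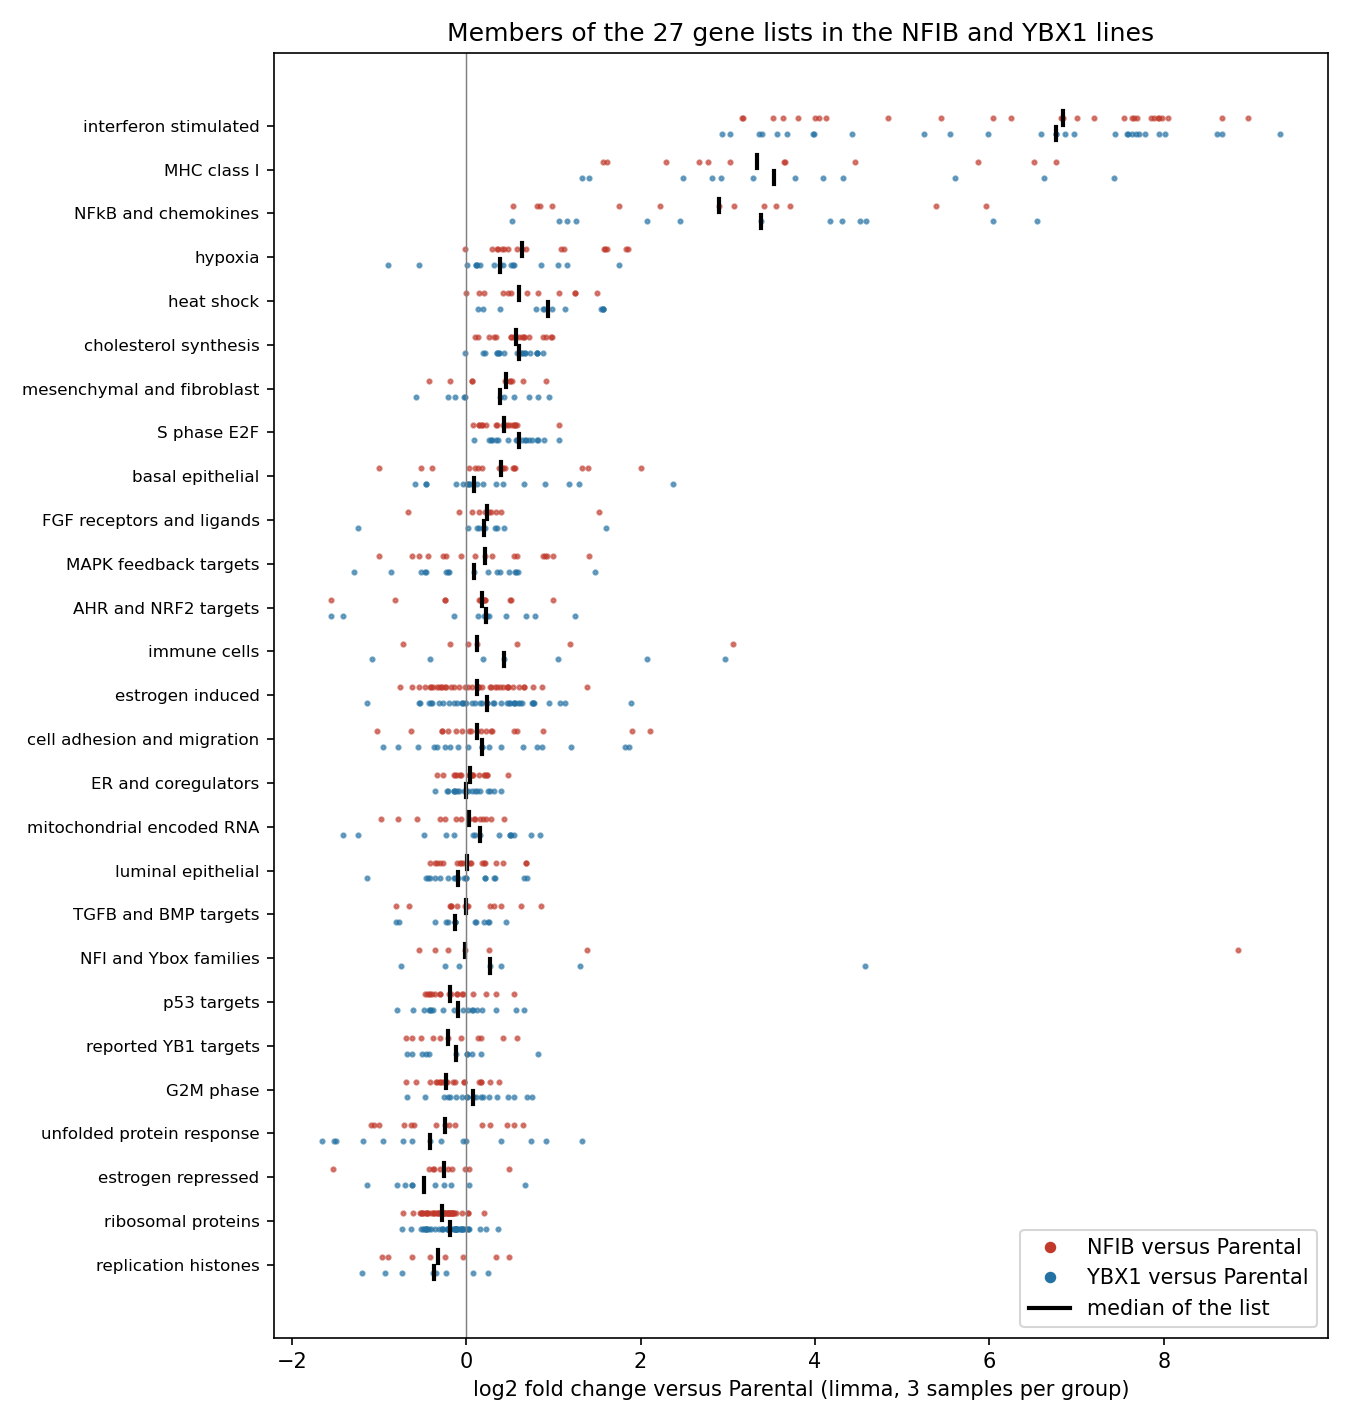
Log2 fold change against Parental (horizontal axis) of each tested member of the 27 fixed gene lists (vertical axis), red for the NFIB line and blue for the YBX1 line; each point is a gene and each black tick a list median, with lists ordered by the NFIB median. The medians of the interferon-stimulated (6.84 and 6.77), MHC class I (3.34 and 3.53) and NF-kB lists (2.90 and 3.38) stood far from those of the other lists, which lay between -0.49 and 0.94.

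Both lines were set against the same Parental libraries, and 8670 genes were called in both in the same direction, 4481 higher and 4189 lower. Ranked by the smaller of the changes in the lines, the largest shared rises were those of GH1, IFI44L, OAS2, IFNL2 and IFIT1B, and the largest shared falls those of CLGN, DMGDH, NIBAN1, DRD1 and TRPV6. Independent lists of these sizes would share 1420.2 higher and 1272 lower genes. In 20 simulations of unchanged groups that share their controls, limma called 0 genes in both lines after adjustment and a mean of 214 (185 to 242) at an unadjusted p under 0.05. Few or no adjusted calls follow from that setting, in which no gene was changed. The simulations also hold no difference common to all Parental libraries, so they cannot measure what such a difference adds to the overlap. Across genes, which are not independent replicates, the correlation of the fold changes was 0.895 against 0.493 in the simulations, the covariance 0.457 against 0.0208, and the share of genes with the same sign 83.7% against 66.5%. Of the shared genes 16.4% also differed between the lines in the direct test, and of 936 genes that changed by at least 1 in both lines in the same direction 171 did. A further 1713 genes were called for NFIB only and 2577 for YBX1 only, which by itself shows no difference between the lines.

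**Figure D3:**
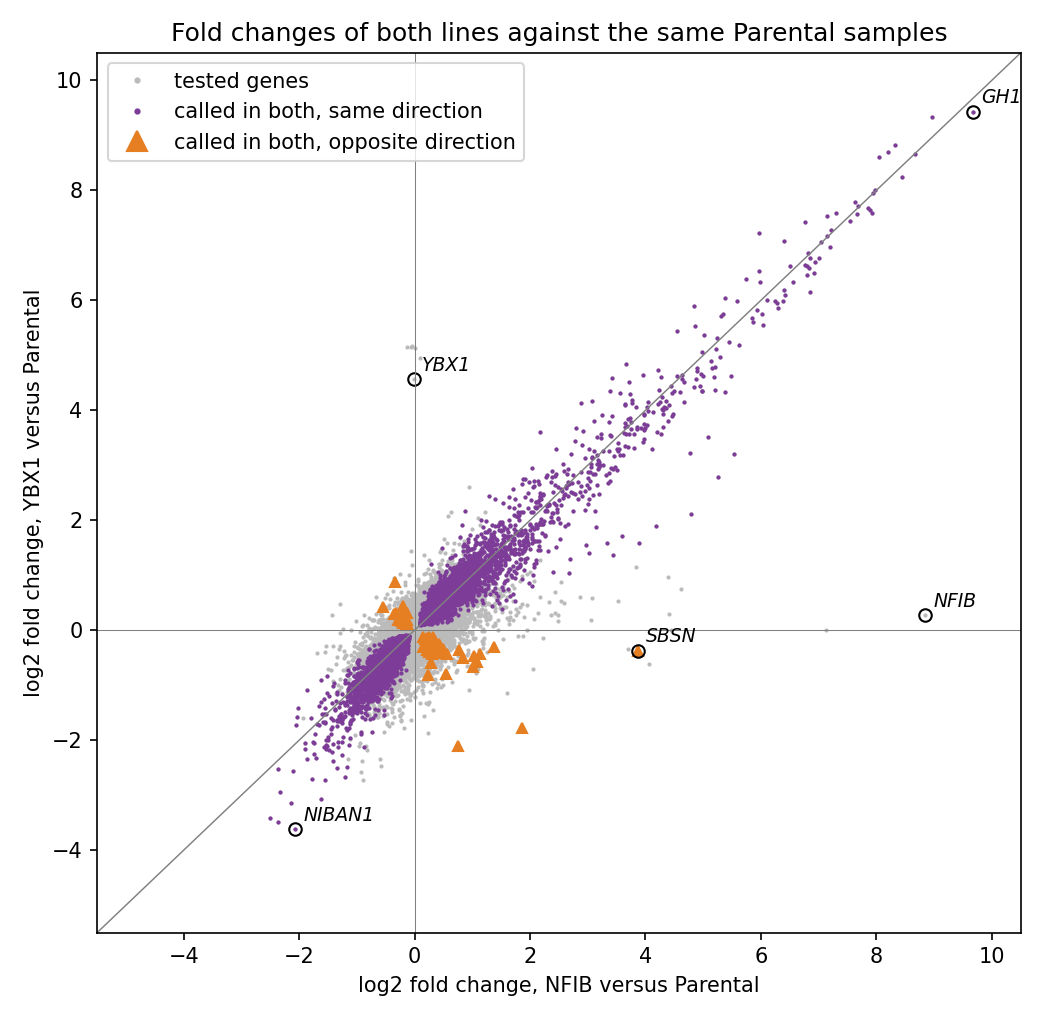
Log2 fold change in the NFIB line (horizontal axis) against that in the YBX1 line (vertical axis), each against Parental, for the tested genes; purple points were called in both in the same direction (8670), orange triangles in opposite directions (59), and the line is the diagonal. NFIB and YBX1 lie away from the diagonal, GH1 lies near it at 9.68 and 9.43, NIBAN1 lies at -2.06 and -3.62, and SBSN lies at 3.87 and -0.37.

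The direct comparison of the NFIB line with the YBX1 line asks what differs between lines that were both transfected and grown with geneticin. SBSN, ANO1 and CDSN were among the genes most raised in the NFIB line, and S100A8 and TNF among those most raised in the YBX1 line. SBSN, which encodes the epidermal protein suprabasin, was higher in NFIB by 4.24 (SE 0.09, limma adjusted p = 1.10e-14), at 1996 ± 152 against 104 ± 1.33 normalized reads. ANO1, a chloride channel gene, was higher by 2.38 (SE 0.14, adjusted p = 5.51e-08), at 435 ± 39.7 against 83.6 ± 15.1, and CDSN, the gene of corneodesmosin, by 2.29 (SE 0.10, adjusted p = 7.51e-10), at 1137 ± 100.1 against 231 ± 21.2. S100A8, a calcium-binding inflammatory gene, was lower in NFIB (-0.91, SE 0.09, adjusted p = 1.95e-05), at 590.2 ± 65.8 against 1109 ± 80.7.

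The other genes most raised in NFIB against YBX1 were CPA4 (2.098), ITGA7 (1.94) and GPD1 (1.83), and those most lowered were KANK3 (-1.30), TNF (-1.25), INPP5D (-1.09), ANK1 (-1.01) and IGFBP6 (-0.90). TNF, at 77.2 in NFIB and 184 in YBX1, was no longer called without NFIB replicate 2 (-1.15, adjusted p = 0.0502), nor was IGFBP6 without NFIB replicate 2 (-0.69, adjusted p = 0.103) or YBX1 replicate 3 (-0.79, adjusted p = 0.0892). Over all alternatives, the deposited scaling included, the adjusted p ranged from 6.79e-09 to 0.9999 for TNF and from 0.000764 to 0.9999 for IGFBP6. Limma called 2809 of 21943 genes (12.8%), 1309 higher and 1500 lower in NFIB, with a median size of 0.26. Only 183 changed by at least 1, with 156 higher and 27 lower. The number of calls depended on single libraries: it was 1408 without NFIB replicate 2, 1535 without YBX1 replicate 3 and 1759 without NFIB replicate 1. The deposited scaling, which moved the median of all genes by 0.15, gave 66 calls, 60 higher and 6 lower (90.9% higher against 46.6% here). Quantile normalization gave 1462 higher and 1383 lower.

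Most G2/M, estrogen-induced and heat shock genes were lower in the NFIB line than in the YBX1 line. In the G2/M list 15 of 20 members were lower, 17 when adjusted over the list alone (median -0.24, camera adjusted p = 9.15e-16, and adjusted p = 0.173 with an estimated correlation). CDC20 was at -0.53 (SE 0.04, adjusted p = 3.08e-06) and PLK1 at -0.48 (SE 0.04, adjusted p = 3.38e-06). In the S phase list 9 of 18 were lower, 13 when adjusted over the list alone (median -0.16, adjusted p = 1.11e-07, and adjusted p = 0.448 with an estimated correlation). MCM4 was at -0.26, and 5 members were lower without NFIB replicate 1 or NFIB replicate 2. In the estrogen-induced list 22 of 41 were lower and 2 higher, 26 and 4 when adjusted over the list alone (median -0.19, adjusted p = 6.63e-09, and adjusted p = 0.173 with an estimated correlation). PDZK1 was at -0.50 (SE 0.05, adjusted p = 1.60e-05), HSPB8 at -0.53 and TFF3 at 0.73. Without NFIB replicate 2, 14 estrogen-induced genes were lower. In the heat shock list 9 of 12 were lower, 10 when adjusted over the list alone (median -0.31, adjusted p = 1.61e-10, and adjusted p = 0.177 with an estimated correlation). HSPA8 was at -0.50. In the ribosomal list 11 of 48 were lower, 15 when adjusted over the list alone (median -0.09, and 0.07 with the deposited scaling, adjusted p = 2.93e-07, and adjusted p = 0.560 with an estimated correlation). RPL38 was at -0.21. The count of lower ribosomal genes was 7 without Parental replicate 1, 3 without any 1 of the NFIB replicates 1, 2 and 3, and 18, 6 and 2 without YBX1 replicates 1, 2 and 3. In the NF-kB list 4 were lower, 7 when adjusted over the list alone (median -0.48, adjusted p = 2.77e-05, and adjusted p = 0.448 with an estimated correlation). TNFAIP3 was at -0.80, and 2 members were lower without NFIB replicate 2 or YBX1 replicate 3.

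Camera placed the hypoxia and interferon-stimulated lists higher in the NFIB line than in the YBX1 line, although most members of each were not called on their own. In the hypoxia list 5 of 17 were higher and 1 lower, 11 and 1 when adjusted over the list alone (median 0.41, camera adjusted p = 7.61e-06, and adjusted p = 0.560 with an estimated correlation). ALDOC was at 1.03 (SE 0.19, adjusted p = 0.00248) and VEGFA at 0.53 (SE 0.07, adjusted p = 0.000279). This difference was not shown by YBX1 replicate 2, which was the highest YBX1 library in all 17 hypoxia genes and reached at least the lowest NFIB library in 14, against 1 each in replicates 1 and 3. ADM, for example, was at 916 there, against 363 and 412 in the other YBX1 libraries and 738 to 873 in NFIB. Without that library 15 of the 17 hypoxia genes were higher (adjusted p = 3.00e-18), and 2 to 3 were without NFIB replicate 2 (2), NFIB replicate 3 (3), YBX1 replicate 1 (3) or YBX1 replicate 3 (2). For hypoxia the adjusted p was 3.00e-18 to 0.560 over all alternatives. In the interferon-stimulated list 7 of 29 were higher, 8 when adjusted over the list alone (median 0.15, adjusted p = 0.000213, and adjusted p = 0.560 with an estimated correlation). MX2 was at 0.50 and RIGI at 0.42, and the number of interferon genes higher was 11 without Parental replicate 1 and 4 without NFIB replicate 1. In the MAPK feedback list 7 of 17 were higher and 1 lower (median 0.17, adjusted p = 0.00304, and adjusted p = 0.391 with an estimated correlation). DUSP6 was at 0.66 and SPRY4 at 0.57. In the estrogen-repressed list 5 of 10 were higher and 2 lower (median 0.16, adjusted p = 0.0312, and adjusted p = 0.274 with an estimated correlation). ERBB2 was at 0.42 and TP53INP1 at 0.37. In the luminal list 3 of 19 were higher and 1 lower, 5 and 1 when adjusted over the list alone (median 0.06, adjusted p = 0.00698, adjusted p = 0.560 with an estimated correlation and 0.231 without YBX1 replicate 1). KRT7 was at 0.51. With the deposited scaling the calls on the interferon (0.0899), MAPK feedback (0.0533), estrogen-repressed (0.314), luminal (0.151) and ribosomal lists (0.102) ended. Over all alternatives the adjusted p ranged from 1.95e-06 to 0.560 for the interferon list, from 0.000322 to 0.391 for MAPK feedback, from 0.00738 to 0.314 for estrogen-repressed, from 8.99e-05 to 0.560 for luminal and from 3.16e-12 to 0.560 for ribosomal genes.

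Among receptor and coregulator genes, whose list camera did not call between the lines, 3 of 19 were higher and 3 lower (median -0.01, 0.14 with the deposited scaling and 0.01 with quantile normalization, mean 0.02, adjusted p = 0.706). AR was at 0.46. Unfolded protein response genes had 7 of 15 higher and 4 lower (median 0.15, adjusted p = 0.0891, but 0.0156 without NFIB replicate 3, 0.0462 without YBX1 replicate 3, 0.0283 with quantile normalization and 0.0493 with edgeR), and ASNS was at 0.56. Of the AHR and NRF2 list 1 of 12 was higher and 2 lower (median -0.12, and 0.03 with the deposited scaling, adjusted p = 0.0519). SLC7A11 was at 0.73. That list was called without Parental replicate 2 (0.0489), NFIB replicate 3 (0.0389), YBX1 replicate 1 (0.0382) or YBX1 replicate 2 (0.0144). It was also called with no filter (0.0129), sample weights (0.0412) and a replicate block (0.0442). Of the MHC class I list 2 of 12 were higher and 4 lower (median -0.12, and 0.03 with the deposited scaling, adjusted p = 0.706). HLA-A and HLA-B, at -0.54 and -0.45, are similar in sequence, and 2 MHC class I genes were lower without NFIB replicate 2, YBX1 replicate 1 or YBX1 replicate 3. Adjusted over the list alone, the counts were 4 higher and 3 lower for coregulators, 8 and 5 for the unfolded protein response, 1 and 3 for AHR and NRF2 targets and 3 and 4 for MHC class I. The adjusted p ranged over the alternatives from 0.0156 to 0.646 for the unfolded protein response list and from 0.0129 to 0.560 for AHR and NRF2 targets. In the FGF list limma called 0 of 10 members, with 1 higher and 1 lower at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 (median -0.01, and 0.14 with the deposited scaling, adjusted p = 0.706). In the immune cell list limma called 0 of 7, with 1 higher and 1 lower at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 (median 0.09, mean -0.17, adjusted p = 0.829). In the mitochondrially encoded list limma called 0 of 15, with 0 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 (median -0.22, adjusted p = 0.298). Without YBX1 replicate 1, which had the lowest mitochondrial share (2.55% of reads), 7 of its 15 members were lower in NFIB (adjusted p = 1.73e-05, against 1.73e-05 to 0.920 over all alternatives).

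Cholesterol, histone, TGF-beta and p53 genes depended on single libraries between the lines. In the cholesterol list 2 of 19 were higher and 1 lower, 3 and 1 when adjusted over the list alone (median 0.07, camera adjusted p = 0.290), with FDFT1 at -0.30. Without YBX1 replicate 2, 8 cholesterol genes were higher and 1 lower (adjusted p = 0.000555, against 0.000555 to 0.979 over all alternatives). In the replication histone list H1-2 was higher (0.27), 1 of 8 members and 2 when adjusted over the list alone (median 0.15, adjusted p = 0.0509). The H1-2 call itself ended without NFIB replicate 1 (0.129), NFIB replicate 2 (0.125), NFIB replicate 3 (0.0534), YBX1 replicate 1 (0.144) or YBX1 replicate 2 (0.0767), and its adjusted p ranged from 0.0108 to 0.9999 over all alternatives. The histone list was called without Parental replicate 1 (0.0406), Parental replicate 2 (0.0429), Parental replicate 3 (0.0498), NFIB replicate 3 (0.0123), YBX1 replicate 2 (0.0150) or YBX1 replicate 3 (0.0121). It was also called with TMM (0.0481), quantile normalization (0.0246), only the 6 libraries compared (0.0395) and a replicate block (0.0342). Its adjusted p ranged from 0.0121 to 0.560 over all alternatives. In the TGF-beta and BMP list ID2 (0.48), ID1 (0.34) and BAMBI (0.26) were higher, 3 of 14 members, 3 higher and 1 lower when adjusted over the list alone (median 0.11, adjusted p = 0.0625). BAMBI was no longer called without NFIB replicate 1 (0.0534), NFIB replicate 2 (0.0869), YBX1 replicate 1 (0.0603) or YBX1 replicate 3 (0.0692), and its adjusted p ranged from 0.000527 to 0.9999. The TGF-beta list was called without NFIB replicate 2 (0.0253) or YBX1 replicate 3 (0.0117). It was also called with DESeq2 (0.0398), no filter (0.0409), quantile normalization (0.0246) and a replicate block (0.0405). Its adjusted p ranged from 0.0117 to 0.546. In the p53 list BTG2 was at -0.39 and TP53INP1 at 0.37, with 3 of 18 lower and 1 higher, 5 and 1 when adjusted over the list alone (median -0.06, and 0.09 with the deposited scaling, adjusted p = 0.257). Without YBX1 replicate 2 its adjusted p was 0.0420, against 0.0420 to 0.971 over all alternatives. The NFI and Y-box list, which holds both transgenes, was not called with limma (2 of 7 higher and 2 lower, also when adjusted over the list alone, median -0.11, mean 0.56 and test direction down, adjusted p = 0.706). It was called lower with edgeR (0.00435) and DESeq2 (0.00196) and higher with the deposited scaling (median 0.04, 1.29e-07), with a range of 1.29e-07 to 0.971.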

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

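The tests of the YBX1 pseudogene reads, of single libraries in the hypoxia list and of the 3 explanations of the interferon rise were chosen only after the result was seen; the other tests here were set before their own results were seen.

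Genes that moved in opposite directions in the lines stand out because the lines differed from Parental with opposite signs. SBSN and 34 further genes, 35 in all, were higher in the NFIB line and lower in the YBX1 line, each against Parental, and 24 genes were lower in NFIB and higher in YBX1. A difference between the lines follows from this choice of genes. Chosen after their values were seen, examples are VTCN1 (1.38 in NFIB and -0.31 in YBX1), CYP4F22 (1.08 and -0.57), KLF10 (-0.19 and 0.44) and UBE2S (-0.26 and 0.21). The mitotic kinase gene PLK1, named by the fixed rule, was at -0.22 and 0.27.

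Estrogen-induced, G2/M and hypoxia genes stand out because camera called each list in only 1 line against Parental and also between the lines. The estrogen-induced list was higher in YBX1 than in NFIB (adjusted p = 6.63e-09), with PDZK1 at 6375 ± 224 against 4509 ± 292 normalized reads (SD, n = 3; limma adjusted p = 1.60e-05). The G2/M list was lower in NFIB (adjusted p = 9.15e-16), with CDC20 at 3539 ± 133 against 5103 ± 239 (adjusted p = 3.08e-06). The hypoxia list was higher in NFIB (adjusted p = 7.61e-06), with ALDOC at 14515 ± 1197 against 7365 ± 2685 (adjusted p = 0.00248). In YBX1 replicate 2, however, 14 of the 17 hypoxia genes reached at least the lowest NFIB library, and without it 15 were higher in NFIB rather than 5. None of the 3 held with an estimated correlation (0.173, 0.173 and 0.560). The 3 libraries of a line allow 10 splits of 6 libraries, too few for a share under 0.05. The real splits gave 10442, 11306 and 2809 genes with limma and in each comparison only 1 of the 10, the real one, gave that many. The highest other split gave 0 genes after adjustment, and 680, 601 and 1483 at an unadjusted p under 0.05 against 11651, 12369 and 5820.

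The interferon-stimulated list rose in both lines by medians of 6.84 and 6.77, and genes of interferons themselves had more reads: over 3 libraries each, IFNB1 had 6 reads in Parental, 1232 in NFIB and 1501 in YBX1, and IFNL1 31, 4550 and 5247 (both chosen after the list was seen). Scaling, which moves all genes of a library alike, is argued against, since the list's reads per read of all other genes but the transgenes were 5.04 higher (log2) in the lowest overexpressing library than in the highest Parental one. Immune cells in the cultures stay open: the 10 members of the immune cell list with values summed to at most 0.30 (log2) above Parental (153 ± 5.07 normalized reads in Parental, 186 ± 10.9 in NFIB and 188 ± 22.5 in YBX1), but members abundant in Parental such as LYZ and CSF1R would hide a small share, and ITGAM was higher in both lines while PTPRC was not. Parental replicate 1 was above both other Parental libraries in 25 of 29 members, at a median excess of 0.428% of the lower line's mean, which is small beside the rise. Transfection, plasmid and geneticin, shared by both lines, cannot be told apart from an effect of NFIB and YBX1, because Parental had none of them; the median between the lines was 0.15, and an effect common to NFIB and YBX1 stays open.

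GH1 rose by 9.68 and 9.43 and lay above every Parental library in 6 of 6 transfected libraries. In untransfected Parental it had 194 reads, at 119, 30.2 and 42.7 normalized reads in replicates 1, 2 and 3. Replicate 1 was also the highest Parental library in 25 of 29 interferon-stimulated genes. The 6 tested of 13 genes around GH1 had a median of -0.19 in NFIB and -0.17 in YBX1, but PRR29, at 6.46 normalized reads in Parental where the other 5 were abundant, was higher in both lines (1.90, limma adjusted p = 0.000197, and 1.51, adjusted p = 0.00130), so activation of the locus stays open. A candidate explanation is growth hormone gene sequence carried by the plasmid, as some mammalian expression plasmids hold a growth hormone polyadenylation signal. The plasmid is not given in the sources used here, so this stays a hypothesis. Such a sequence would not by itself account for the GH1 reads in untransfected Parental.

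All 4 tested YBX1 pseudogenes (YBX1P1, YBX1P2, YBX1P6 and YBX1P10) rose in the YBX1 line, with a median of 5.15 against 4.57 for YBX1. A general rise of processed pseudogenes is argued against, since 2500 others had a median of -0.0152. Reads of the transgene counted on these near-identical copies may account for the rise. If so, the YBX1 count leaves out part of the transgene's reads. In the YBX1 line YBX1P1 reached 22.99% and YBX1P10 11.02% of the YBX1 level. In Parental, without a transgene, they already stood at 2137 and 1028 normalized reads, so such shares alone do not show reads of the transgene. Transcription of the copies themselves was not tested. In the NFIB line the 4 were not called, at -0.07 to 0.10.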

How the results depend on the processing

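With the deposited values as they stand, an alternative added after the data were seen, the calls dropped to 871 for NFIB against Parental, 1167 for YBX1 against Parental, 66 between the lines and 632 shared, and the estrogen-induced list was no longer called in YBX1 (adjusted p = 0.204). Of these calls 861, 1157 and 65 were also called with division by the size factor. The construction shows the cause: multiplying by the size factor leaves medians of tested genes 2.01 times apart between libraries. NFIC between NFIB and YBX1 reversed there, to 0.0112 from -0.14. Requiring a change of at least 1 left 1305, 1544 and 183 genes by construction, and an estimated correlation gave adjusted p = 0.410 for estrogen-induced genes in YBX1; the cause was not tested. In refits without 1 library, which leave 2 in its group, the calls ranged from 9114 to 10573 for NFIB, from 10186 to 11125 for YBX1, from 1408 to 3022 between the lines and from 7597 to 8380 shared. Estrogen-induced genes ranged from 0.230 to 0.395 in NFIB and from 0.00243 to 0.0142 in YBX1, NFIB itself from 8.75 to 8.96 and YBX1 from 4.48 to 4.64. The other alternatives gave 9802 to 11342, 10523 to 11566 and 2476 to 3003 calls, all within 1.5 times the main counts. DESeq2 gave 9941, 10654 and 3003 and edgeR 10582, 11364 and 2970. Size factors without interferon genes and transgenes, also added after the data were seen, gave 10432, 11302 and 2816. The replicate numbers as a block gave 10436, 11282 and 2887, and they do not pair the libraries: correlations of same-numbered libraries ran from -0.0869 to 0.0857, and 3 of 9 libraries correlated best with their own number. Of 344 results on named genes, 295 kept their side of the threshold in each alternative but the deposited values, where 209 lost their call. Leaving out single libraries ended a call 148 times and made one 2 times, mostly between the lines, as for TNF, and also against Parental, as for FGFR2 in NFIB.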

Other observations

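The tests of epidermal genes against Parental in both lines, and of amino acid response genes in NFIB against Parental and NFIB against YBX1, were chosen only after the result was seen, as were the members named here.

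Amino acid response genes, which respond to ATF4 under amino acid shortage, were lower in both lines. The list was made because ALDH1L2, INHBE and NIBAN1 fell, and it leaves those out. Those falls were seen in the same libraries, so the tests of this list are not independent of them. Its p-values are also not adjusted over lists, unlike those of the fixed lists. They therefore cannot show that this list holds better than the fixed lists do. In the YBX1 line 30 of 31 tested members fell (31 when adjusted over the list alone), with a median of -0.85 (camera p = 1.17e-20, and p = 0.0393 with an estimated correlation). In the NFIB line 28 fell, with a median of -0.62 (p = 2.49e-17, and p = 0.0544 with an estimated correlation). Between the lines 25 members were higher in NFIB and 1 lower (26 and 1 when adjusted over the list alone; median 0.22, p = 3.58e-19, and p = 0.0452 with an estimated correlation). CEBPG, a transcription factor gene of this response, fell by 1.09 in NFIB and by 1.48 in YBX1. The aminoacyl-tRNA synthetase gene SARS1 fell by 1.05 and by 1.38, and the serine synthesis gene PHGDH by 0.77 and by 1.12. FGF21, a hormone gene of the same response, fell by 1.42 and by 2.37. The medians kept their signs with TMM, quantile and the deposited scaling (-0.88 for YBX1 with quantile normalization and -1.04 with the deposited scaling). Lower amino acid stress in the lines is a hypothesis for these falls and was not tested. A difference in cell density or medium at harvest was not tested either.

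Of 29 tested epidermal differentiation genes other than those that prompted the list, 7 were higher in NFIB than in YBX1 and 22 were not called (8 higher and 2 lower when adjusted over the list alone; median 0.16, camera p = 0.00234, and p = 0.115 with an estimated correlation). Against Parental, however, 8 members were lower and 6 higher in the NFIB line (median -0.07; camera p = 0.364, and p = 0.603 with an estimated correlation). In the YBX1 line 12 were lower and 5 higher (median -0.18; camera p = 0.0314, and p = 0.241 with an estimated correlation). Since members went both ways, no rise of epidermal genes as a group with NFIB was seen against Parental, though the test cannot exclude one. Of the 7 members higher in NFIB than in YBX1, ABCA12, TGM1 and PPL had lower means in NFIB than in Parental. CASP14, KLK5, SPRR1B and IVL had higher ones. SBSN and CDSN, which prompted the list, rose by 3.87 and by 3.88 in NFIB, but in the YBX1 line SBSN fell by 0.37 while CDSN rose by 1.59. The p-values of this list, prompted by genes seen in the same libraries, are not adjusted over lists either.

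Neighbouring genes changed together more often than shuffled orders gave. Of 830 windows of 25 neighbouring tested genes, 29 had a median beyond 0.3 in either line, against a mean of 4.07 and at most 11 in 1000 shuffled orders. Of these 23 were higher, 9 lay beyond in both lines in the same direction, and 1 pair was adjacent. Gained or lost chromosome segments could give this (29 windows). Families of co-regulated neighbours could also do so in some windows, which held MHC class I, S100, KLK, keratin or histone genes. Such families would not cover the windows without them.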
